A study of Sus scrofa with 18 samples.

How the data were processed

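RNA from the longissimus dorsi, the long muscle of the back, was compared between Landrace and Taihu pigs at 6 ages, months 0 to 5, where month 0 is the newborn piglet. Each of the 12 combinations of breed and month gave 1 RNA label. Per the labels' protocols, tissue was kept in RNAlater, total RNA was extracted with a column kit for fibrous tissue, and RNA was amplified linearly and labelled with Cy3 or Cy5. There were 18 arrays. On 6 of them the breeds were hybridised against each other at the same month, with Landrace always in Cy3 and Taihu always in Cy5. The other 12 formed 1 closed loop per breed (6 arrays each), in which each month was set against the next and month 0 against month 5, so that each RNA stood once in Cy3 and once in Cy5. Each RNA was therefore on 3 arrays. The labels do not say whether an RNA came from 1 animal or a pool, and the arrays reuse the same RNA labels, so the p-values measure the spread between hybridisations, which may be technical only.

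Per the file headers, the deposited intensity values were quantified in the format of ImaGene version 5.1 with fixed circles, a background buffer of 3 and a background width of 5, and empty spots were marked. The 36 channel files hold the mean signal and the median background of 656 spots in 8 blocks of 82. The blocks were 2 panels printed 4 times each, as found from the values: the 4 copies of a position had a median correlation over arrays of 0.968, against 0.453 between neighbouring positions. The opening 12 positions of each block had like levels in both panels and no value on any array in the authors' table, and were treated as controls. This left 140 probes with 4 spots each. The files do not pair spots with genes, so probes are named here by their panel, row and column as the files write them. The gene lists, marker lists, reference-gene centring and the rule for named genes that were fixed beforehand could not be used. In their place at most 2 probes that rose and 2 that fell are printed per comparison, those with the largest changes past the threshold.

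The authors also deposited a table of log2 values for the same spots. Set against the scanner values of each array, it ran as log2 of Cy3 over Cy5, opposite to the direction used here, with a correlation of 0.698 to 0.945. Over all arrays the correlation was 0.70 with the panels matched and -0.06 with the panels exchanged. Its normalization and centring stay unknown. The column medians of the Landrace loop, replicates 1 to 6, were -0.06, -0.06, 0.0036, 0.02, 0.00056 and -0.10. Those of the Taihu loop were 0.016, -0.13, -0.17, 0.029, -0.13 and -0.07, and those of the breed arrays -0.15, -0.33, -0.11, -0.03, -0.08 and -0.03. Between 311 and 428 spots per array had a value there. It served only as an alternative.

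Analysis used limma 3.58.1 in R 4.3.3. Background was corrected with normexp at an offset of 50, ratios of Cy5 over Cy3 were normalized by loess within each array at a span of 0.3 with controls at no weight, flagged spots (29 of 10080 probe spots) were left out, and the log2 ratios of a probe's spots were averaged. The median SD over the spots of a probe within an array was 0.07. One linear model per probe over the 18 arrays had 12 coefficients, 11 differences between RNAs and a dye intercept of the probe, and left 6 residual degrees of freedom, to which the moderation added 2.93. In this design the dye intercept equals the mean of the 12 loop arrays, and the breed average equals the mean of the 6 breed arrays less that intercept. Loop arrays of the same months in the 2 breeds always have residuals of equal size and opposite sign, so residuals cannot tell which of the pair stands apart. Any failure of the loops to close that both breeds share enters the dye intercept, and through it the breed average.

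Contrasts were tested two-sided with limma's moderated statistics and month effects with its moderated F, each adjusted by Benjamini-Hochberg over the 140 probes, with a threshold of 0.05. All adjusted p-values below are of this kind. A spot with a mean signal of 60000 or more was counted as saturated, and a probe was well above background when its signal exceeded the background by 2 background SDs. For a probe saturated in all 3 channels of an RNA, the fold is given as "at least" the lowest of 3 ratios: that of the normalized channel values after loess and quantile scaling of average intensity, and those of the geometric and the arithmetic means of the raw signals. Both months compared hold the same number of channels in each dye. This bound allows for saturation only, not for the spread of the signals between arrays. No fold is given where the signals of 1 RNA disagree widely between arrays. On simulated data with this design and these residual SDs, with 40 of 140 probes changed in each of 20 simulations, the breed average recovered 78.0% of changes of 0.25 log2 and 96.8% of changes of 0.5. The change from month 0 to 5 in Landrace recovered 40.4% and 87.0%, and the interaction test 1.38% and 68.6%.

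Alternatives fixed before the data were examined were median centring, no normalization, quantile scaling of average intensity, no background correction, a normexp offset of 10, leaving out the dimmest 25% of probes, no dye intercept, array weights, the median over spots, the authors' table, the breed arrays alone, the loops without the breed arrays, and leaving out each array. Leaving out the probes with incomplete values in the authors' table and leaving out the saturated probes were chosen after seeing the data. The scan dates were blank, so no batch by date was tested.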

Results

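The series set a lean-type breed, Landrace, against a fat-type breed, Taihu, in the longissimus dorsi muscle from birth to month 5. It asked which transcripts differ between the breeds and which change with age. The array held 140 probes besides its controls. Median probe signal per array ran from 848.8 to 1738 in Cy3 and from 741.6 to 2024 in Cy5. Of the 140 probes, 4 were not well above background in at least 1 of the 36 channels, and none in every channel. At the bright end 16 probes were saturated in 1 channel or more, and 9 in at least 18 of the 36 channels. Residual SDs of single probes had a median of 0.11 on the log2 scale and a range of 0.03 to 0.46. The number of arrays limits the precision. The files do not pair spots with genes, so the probes below carry their position on the array as a name.

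The first comparison asked how the breeds differ over the whole period. Averaged over the 6 months, 24 probes were higher in Taihu and 36 lower, 60 of 140 in all. Each breed and month has a single RNA label, so all comparisons here are between the RNAs behind these labels. Over all 140 probes the median size of the difference was 0.12 on the log2 scale, and none of the 60 called probes reached a change of 2-fold. Probe Sr02R04C06 was the highest in Taihu relative to Landrace, at a log2 difference of 0.89 ± 0.09 (SE, adjusted p = 6.86e-05), and lay above 0 at all 6 months, from 0.31 at month 2 to 1.70 at month 4. Sr01R04C09 followed at 0.72 ± 0.06 (adjusted p = 2.70e-05), also above 0 at all 6 months. Sr01R06C01 was lower in Taihu, at -0.61 ± 0.04 (adjusted p = 4.16e-06), and below 0 at all 6 months. Sr01R05C08 had the most negative estimate, -0.75 ± 0.18 (adjusted p = 0.00797), but it was saturated in 26 of 36 channels and its mean on the 6 breed arrays alone was -0.16 (adjusted p = 0.199). Its call was also lost with median centring (-0.32, adjusted p = 0.152), and that of Sr01R04C09 without normalization (0.36, adjusted p = 0.0612). Sizes moved too: Sr02R04C06 had 0.47 without normalization and 1.60 in the deposited table, where it lacked a value on 1 array or more. Sr01R06C01 had -0.98 without normalization and -0.37 without the dye intercept.

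Which probes were called, and their split, depended on the setting. With the dye intercept left out, 31 probes were higher and 26 lower, and 47 of these 57 were among the 60 in the same direction. The values deposited by the authors gave 23 higher and 5 lower, out of 92 probes, and 21 of these 28 were among the 60. Without normalization 1 was higher and 95 lower, with the median of all probes at -0.49. Of these 96, 35 were among the 60 in the same direction and 1 in the opposite direction. Exchanging the breed labels within months gave at least 60 calls in 4 of the 32 distinct ways, the real one included, so the count itself was not beyond that of other groupings of the same RNAs.

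Taken month by month, the breed comparison gave 301 calls over the 6 months. The sum was 138 without the dye intercept, 156 without normalization and 145 in the deposited table, where only 92 probes could be fitted. Month 0 had 21 probes higher and 32 lower in Taihu, month 1 had 24 and 31, and month 2 had 23 and 31. At month 3 there were 20 and 21, at month 4 there were 28 and 28, and at month 5 there were 16 and 26. In all, 106 probes were called at 1 month or more. Only 2 were called lower in Taihu at all 6 months, and 0 were called higher at all 6, although the number called at a single month ran up to 56. The direction changed between months for 36 probes, which were called higher at some months and lower at others. Of the 60 probes called on the average, 23 had the same sign at all 6 months, and 47 also passed the F test of the interaction of breed and month given below. Each monthly difference had a root mean square size between 0.32 and 0.40, against an SE of 0.11.

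**Figure D1:**
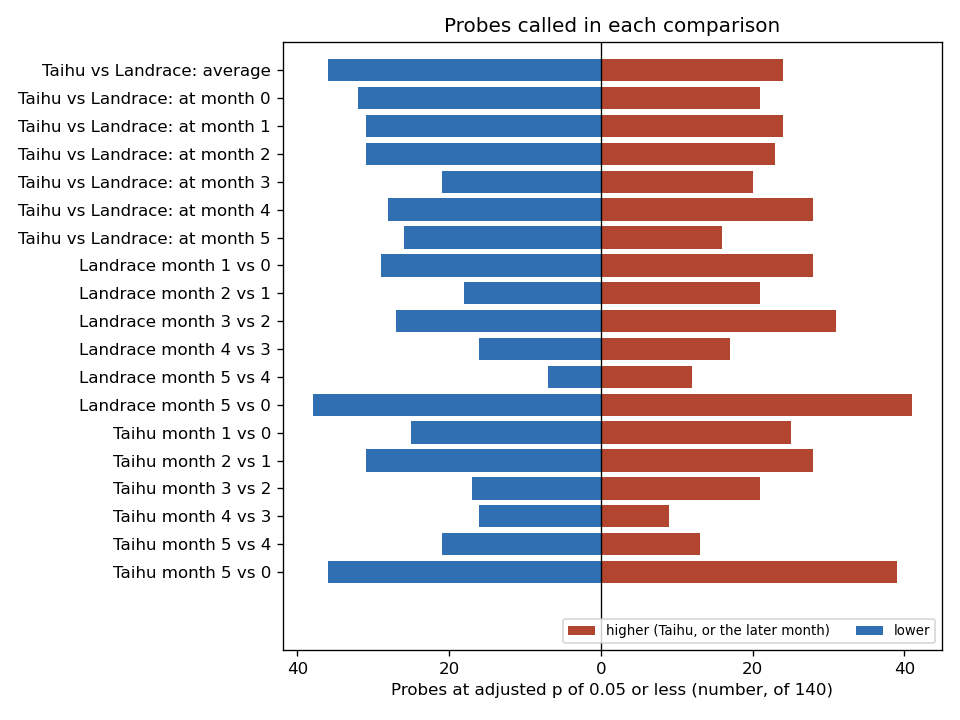
Bars give the number of probes (of 140) at an adjusted p of 0.05 or less in each comparison, with those higher in Taihu or at the later month to the right and those lower to the left. The changes from month 0 to 5 have the longest pairs of bars (41 higher and 38 lower in Landrace, 39 and 36 in Taihu), and the step from month 4 to 5 in Landrace the shortest (12 and 7).

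The second set of comparisons asked what changes with age within a breed. In Landrace 86 of 140 probes changed over the 6 months by the moderated F test, and in Taihu 95 did. Both lists shared 78 probes, where independent lists of these sizes would share 58.4. The lists are not independent, since both tests use the same residual spread of a probe, so probes of low spread tend to enter both. In both breeds more probes had their highest or their lowest level at month 0 than at any other month: 27 highest and 30 lowest of the 86 in Landrace, and 27 highest and 36 lowest of the 95 in Taihu.

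From month 0 to 5, 41 probes rose and 38 fell in Landrace. Of these 79, 25 changed at least 2-fold. Without normalization 54 probes were called, 13 higher and 41 lower, with the median of all probes at -0.31. Of these 54, 45 were among the 79 in the same direction. Sr02R06C05 rose at least 5.58-fold (adjusted p = 1.46e-07; 7.40-fold on normalized values). It was saturated at month 5 in all 3 channels, with month 0 signals of 6548, 7425 and 20989, a spread that the bound does not cover. Sr01R05C08 rose too (adjusted p = 7.50e-07), but no fold is given, because month 5 was saturated and its month 0 signals disagreed, with 2549 beside the month 5 RNA but 35452 and 46377 on the other arrays. Sr01R07C02 fell, with a log2 change of -2.42 ± 0.18 (SE, adjusted p = 2.22e-06), and Sr02R03C03 fell with -2.33 ± 0.13 (adjusted p = 4.81e-07). Each was saturated in 1 of its 3 Landrace month 0 channels, with signals of 64828 and 64372, so these sizes are not exact.

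In Taihu 39 probes rose and 36 fell from month 0 to 5, and 26 of these 75 changed at least 2-fold. Without normalization 41 probes were called, 15 higher and 26 lower, with the median of all probes at -0.14. Of these 41, 39 were among the 75 in the same direction. Sr02R06C05 rose at least 11.9-fold (adjusted p = 2.95e-08) and was saturated at month 5. Sr01R05C08 rose as well (adjusted p = 7.10e-07), again with no fold given, since month 5 was saturated and the month 0 signals disagreed, with 2869 beside month 5 and 26214 and 22388 elsewhere. Sr01R07C02 fell, at -2.90 ± 0.18 (adjusted p = 7.10e-07), with 1 of 3 month 0 channels saturated, and so did Sr01R04C09, at -2.25 ± 0.09 (adjusted p = 7.64e-08).

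Across the 140 probes, which are not independent replicates, the changes from month 0 to 5 in the 2 breeds had a Pearson correlation of 0.911 and a Spearman correlation of 0.783. Over the 124 probes saturated in no channel the Pearson correlation was 0.844. Their covariance was 0.895, against 0.0038 that the shared arrays add through error. Both breeds called 58 probes. Of these, 29 rose in both, 27 fell in both and 2 went opposite ways, where independent lists would share 11.4 rising and 9.77 falling probes. These lists too share the residual spread of each probe and are not independent.

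**Figure D2:**
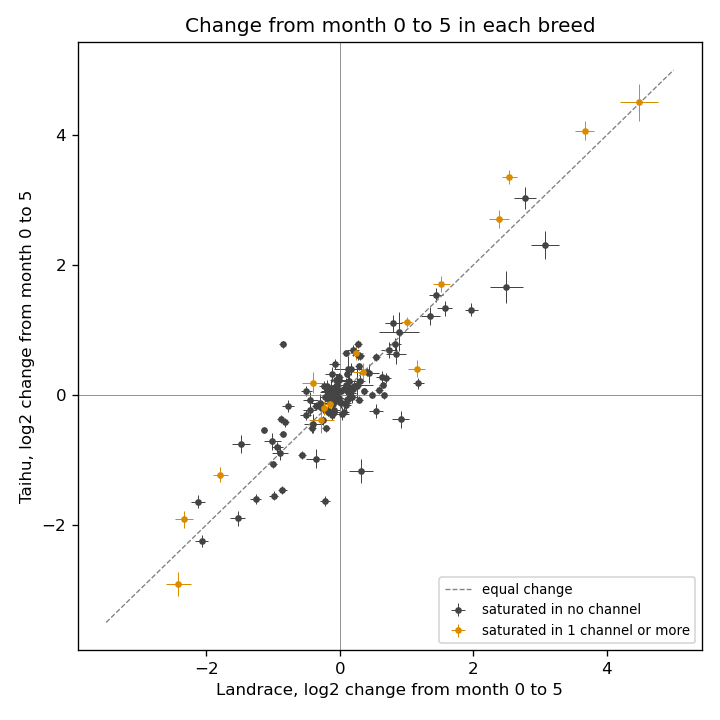
Each point is 1 of the 140 probes, with its log2 change from month 0 to 5 in Landrace on the horizontal axis and in Taihu on the vertical axis, bars giving the SE and colour marking the 16 probes saturated in 1 channel or more. Points scatter about the line of equal change (Pearson correlation 0.911, or 0.844 without the saturated probes, and Spearman 0.783). For 50 of the 140 probes the change was called different between the breeds. The fitted values of saturated probes at the upper right are not reliable as sizes.

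Step by step, Landrace had 28 probes higher and 29 lower at month 1 than at month 0, 21 and 18 from month 1 to 2, 31 and 27 from month 2 to 3, 17 and 16 from month 3 to 4, and 12 and 7 from month 4 to 5. Taihu had 25 and 25, 28 and 31, 21 and 17, 9 and 16, and 13 and 21 in the same order. Each breed summed to 206 calls. The sums were 93 in Landrace and 82 in Taihu without the dye intercept, 43 and 48 without normalization, and 37 and 41 without the breed arrays. In the deposited table, with 92 probes fitted, they were 112 and 122. The root mean square change of the first step was 0.60 in Landrace and 0.61 in Taihu, and that of the step from month 4 to 5 was 0.26 and 0.34. The correlation across probes between the breeds' steps was 0.856 for the first step, 0.738 for the second, 0.378 for the third, 0.20 for the fourth and 0.272 for the last.

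With no dye intercept the month effect was called for 55 probes in Landrace and 58 in Taihu. By the design every month estimate stays the same there, and the median residual SD rises from 0.11 to 0.23. With the breed arrays left out the month effect was called for 47 and 35 probes, on fewer arrays, while the changes of Sr01R07C02 from month 0 to 5 were -2.55 in Landrace and -2.77 in Taihu.

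The last comparison asked whether the breeds change differently with age. The interaction of breed and month passed the moderated F test for 82 of 140 probes. The change from month 0 to 5 itself differed for 50 probes, more upward in Taihu for 26 and more downward for 24. Sr01R07C01 fell in Landrace, at -0.85 ± 0.05, and rose in Taihu, at 0.78 ± 0.05, a difference of 1.63 ± 0.06 (adjusted p = 6.50e-08). Sr01R06C06 rose in both breeds, with fitted changes of 2.54 ± 0.11 in Landrace and 3.36 ± 0.11 in Taihu and a fitted difference of 0.82 ± 0.13 (adjusted p = 0.00107), but it was saturated in 21 of 36 channels, among them 2 of the 3 month 5 channels in each breed, so neither the rises nor their difference were measurable in size. Sr02R05C09 fell in Taihu, at -1.64 ± 0.08, and had -0.22 ± 0.08 in Landrace, a difference of -1.42 ± 0.09 (adjusted p = 4.78e-06). Sr02R05C02 had a fitted fall in Taihu of -1.17 ± 0.18, against 0.32 ± 0.18 in Landrace, a difference of -1.50 ± 0.21 (adjusted p = 0.000562). Its raw signals for Taihu month 5 disagreed, with 1131 beside month 0 but 354 and 475 on the other arrays. For Taihu month 0 they were 915 beside month 5 and 743 and 800 elsewhere. The size of its change is therefore uncertain.

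The interaction was called for 34 probes with no dye intercept, where the estimates stay the same and only the error grows, and for 13 without normalization. The difference in the change from month 0 to 5 was called for 7 probes upward and 10 downward with no dye intercept. Without normalization it was called for 1 upward and 3 downward. In the authors' table, with 92 probes fitted, it was called for 8 probes upward and 20 downward, with a median over all of them of -0.15. The call of Sr01R06C06 was lost in the authors' table (0.49, adjusted p = 0.102) and without normalization (0.85, adjusted p = 0.197). That of Sr02R05C02 was lost without the dye intercept (adjusted p = 0.0691) at an unchanged -1.50. Leaving out the array of month 0 against month 5 of either breed brought Sr01R06C06 to 0.54 and Sr02R05C02 to -1.99. In the deposited table Sr01R07C01 had 2.54 and Sr02R05C09 -2.18, but both lacked a value there on 1 array or more. Sr02R05C02 was incomplete there too and gave no fitted value.

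**Figure D3:**
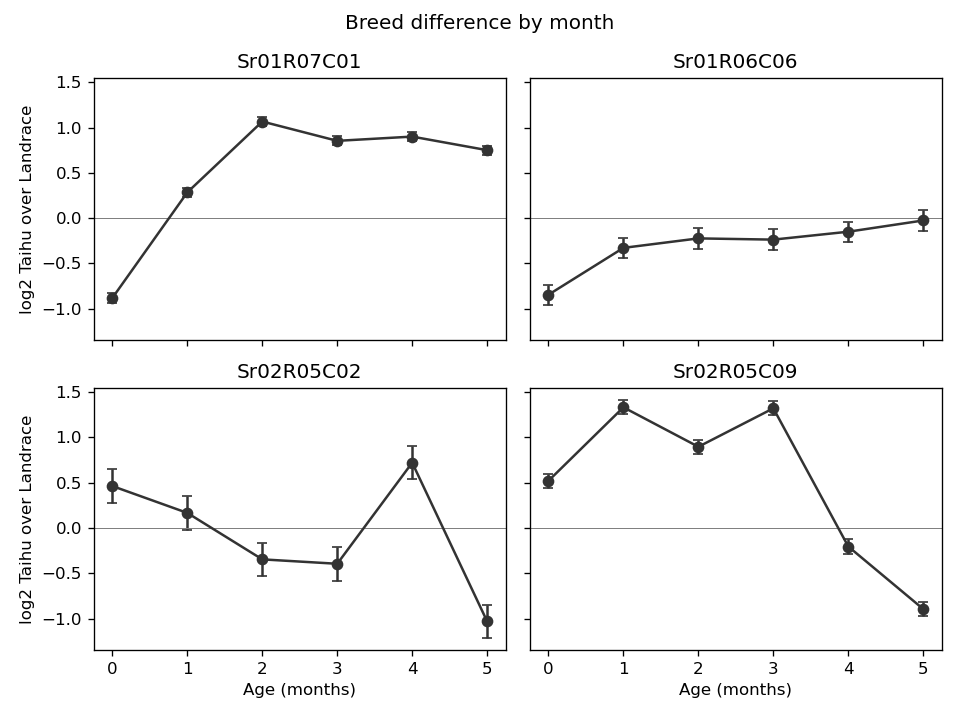
Each panel plots the log2 level in Taihu over that in Landrace against age in months for 1 probe, with bars giving the SE of the joint fit. Sr01R07C01 moves from -0.88 at month 0 to 1.07 at month 2, while Sr02R05C09 moves from 1.32 at month 3 to -0.90 at month 5.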

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

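The tests of loess and of saturated probes below were chosen after their results, or related ones, had been seen. Chance flags about 1 in 20 groups examined for an array far from the others, and 18 groups of 6 were examined. The 2 arrays of month 0 against month 5 had a residual root mean square of 0.137, where the other loop arrays lay between 0.058 and 0.078. By the design the 2 share this value, so it is 1 finding, and it does not show which of them is out of place. Of the breed arrays, that of month 0 had 0.142, the highest of all 18, and that of month 5 had 0.108, where the other 4 lay between 0.064 and 0.082. The fifth breed array had 13 flagged probe spots, where the other breed arrays had 0 to 2.

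The interaction of breed and month was called for 82 probes. Each breed and month has 1 RNA label, and the labels do not say whether its arrays shared 1 extract. The error is the spread between hybridisations, which may be technical only, so the test sets these RNAs apart, not the breeds in general. In the change from month 0 to 5 the breeds differed by 1.63 for Sr01R07C01 and 0.82 for Sr01R06C06 (saturated in 21 of 36 channels, so not measurable in size). The difference was -1.42 for Sr02R05C09 and -1.50 for Sr02R05C02 (-1.99 on leaving out either array of month 0 against month 5). With 1 aberrant array as the source the count was predicted to fall sharply without it, but the lowest count on leaving out any of the 18 arrays was 64. For the interaction, leaving out a loop array or its partner in the other breed gives the same fit. Without either array of month 0 against month 5 the count rose to 94. An aberrant array can also widen the error, so the lack of a fall does not exclude one. Loess fitted to few probes was tested with median centring, which gave 74. Median centring also takes the middle of the same few probes as unchanged, so a like count cannot exclude an artefact of normalization. A like count can also hold other probes, and the 74 were not compared with the 82 probe by probe. The interaction count was 34 without the dye intercept, with the same estimates and a larger error. It was 13 without any normalization, where Sr01R07C01 had 1.94, Sr02R05C02 -1.33 and Sr02R05C09 -1.07. These RNAs cannot tell a difference in development between the breeds from differences between the animals behind each RNA, so both stay open. The month profiles of the breeds are compared further below.

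The breed average, with 60 probes, was weighed against 3 technical explanations. Dye bias as the whole source argues for few of the breed arrays' own calls surviving the dye intercept: 57.4% of those on the breed arrays alone did (27 of 47). In that fit, which also lacks the 12 loop arrays, 33 of the 60 calls were not called. Each of its 6 arrays is a different month. Its error thus holds the month-to-month spread of the breed difference, which the joint fit leaves out of its error. The 33 therefore do not measure the dye effect alone. When only the intercept was left out, 47 of 57 calls were shared with the 60 in the same direction, and 13 of the 60 were missing. The dye intercept was called for 95 of 140 probes, with an SD over probes of 0.28 against 0.24 for the breed average. It correlated with the mean of the breed arrays across probes (0.808), so a large part of those arrays' signal goes with the dyes. Without the saturated probes the count was 58. The dye intercept followed the age change across the 16 saturated probes (correlation 0.615) but not across the other 124 (0.03), so single saturated probes such as Sr01R05C08 remain doubtful. Chance could not be excluded, since 4 of the 32 ways of exchanging breed labels gave as many calls, with 65 as the highest other count, which goes with the many probes whose breed difference changes sign between months.

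Of the 24 control positions, which the comparisons did not use, 2 had every spot flagged on 1 array or more and were left out, and 16 of the other 22 differed between the 12 RNAs by limma's moderated F test. The residual SD was at most 0.5 times the SD of the fitted levels at 9 of these 16 and above it at 7. The widest range of fitted levels was 2.95 on the log2 scale, at position 2 of the first panel, with 2.84 at the same position of the second. Across the 12 RNAs the levels of a position correlated between the panels at 0.697 to 0.998. Both panels lie on the same arrays, so errors of a hybridisation can repeat between them as well as differences between RNAs. Positions 4, 9, 10 and 11 lay lower in Taihu than in Landrace at each month in both panels, and no position lay higher at each month. Of these, position 10 of the first panel (adjusted p = 0.376 over the 22 positions) and position 11 of both panels (0.23 and 0.232) did not pass the F test. What these positions hold is not known, and whether their differences bear on the breed calls was not tested.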

How the results depend on the processing

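Of 277 counts under alternatives, 245 stayed within 1.5 times the main count and 32 did not. Of 478 values of printed probes, 0 reversed and 7 lost their call. These tallies include settings that could not move an estimate. Quantile scaling of average intensity changes no ratio and tests nothing here. Leaving out dim, incomplete or saturated probes keeps the estimates of the others. The printed probes were also chosen for their large changes in these data. A like count can hold other probes: median centring gave 68 for the breed average, of which 47 were among the 60 main calls in the same direction. The causes of the moves below were not tested, with these exceptions: without the dye intercept the month and interaction estimates stay the same and the error grows, and without the breed arrays fewer arrays enter. The authors' table has fewer probes to test, beside its unknown normalization, and the probes complete in it are fewer still. Without normalization the counts were 96 for the breed average, 156 for the breed at each month, 41 and 46 for the month effect in Landrace and Taihu, 43 and 48 for adjacent months, 41 for month 5 against 0 in Taihu and 13 for the interaction. Without the dye intercept they were 138 for the breed at each month, 55 and 58 for the month effects, 93 and 82 for adjacent months, 52 and 49 for month 5 against 0, and 34 for the interaction. With the breed arrays left out the month effects were 47 and 35 and adjacent months 37 and 41. In the authors' table (92 probes) they were 28 for the breed average, 145 for the breed at each month, 60 for the month effect in Taihu, 112 and 122 for adjacent months, 46 for month 5 against 0 in Taihu and 46 for the interaction. On the 74 probes complete in that table, chosen after seeing the data, they were 37 for the breed average, 185 for the breed at each month, 61 for the month effect in Taihu, and 52 and 46 for month 5 against 0. Leaving out single arrays gave 43 to 70 for the breed average, 243 to 353 for the breed at each month, 75 to 94 and 81 to 101 for the month effects, 151 to 253 and 152 to 261 for adjacent months, 65 to 86 and 59 to 77 for month 5 against 0, and 64 to 94 for the interaction. Saturation limits the bright end. Reference-gene centring, the list tests and their estimated correlation were not run, since the files do not pair spots with genes.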

Other observations

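The hypothesis that the breeds pass through the same profile at the same month was tested with each breed's own mean per probe removed. At months 0, 1, 2, 3 and 5 the nearest Landrace month to Taihu was the same month, in 81.2% to 100% of 1000 resamplings of the probes. Taihu month 4 was nearest to Landrace month 3, at a root mean square distance of 0.28 against 0.32 to Landrace month 4, in 97.3% of them. Thus 1 Taihu month of 6 passed the bound set beforehand, which is consistent with a lag of Taihu at month 4. Probes were resampled and not animals, so a peculiarity of a single RNA at that month remains as open as a lag.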
